A study of Arabidopsis thaliana with 6 samples.

How the data were processed

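RNA-seq values of 4 libraries and 1 ChIP-seq peak list were analysed, all from whole seedlings of Arabidopsis thaliana. Samples were put in groups by their genotype and medium in the labels, with 1 library per group. The seeds had 4 days of cold at 4 °C and then grew at 22 °C under continuous light, per the labels. Before the data were examined, the comparisons, the gene lists, the rule for naming genes and the alternatives to be tried were fixed.

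The FPKM values were made by the authors with Cufflinks from reads mapped with TopHat to TAIR10, with uniquely mapped reads alone, per the submitters' processing notes and series description. Reads were processed with CASAVA 1.8.2, per the same notes; the versions of TopHat and Cufflinks are not given in the sources used here. Reads from near-identical gene copies are lost or reduced by that choice. Library totals ran from 4383940 to 4694640 FPKM, and the scaling behind them is not given in the sources used here. First-strand cDNA was primed with random hexamers, per the series description, and no source used here gives a stranded kit, so reads of overlapping genes on opposite strands cannot be separated. No read counts were used here. Low values were examined for steps of whole reads: among genes with low values the commonest log2 ratio to wild type with copper was 0.02 for wild type on MS, -0.09 for spl7 on MS and 0.11 for spl7 with copper, but these held 6.46%, 3.45% and 5.61% of the genes. Depth was therefore taken as unknown, and no counting interval is given for FPKM.

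The peaks carry names of the MACS peak caller and a score, both as deposited by the authors, after mapping with Bowtie to TAIR10, per the submitters' processing notes. What the score measures, the version and threshold of the caller, and whether the spl7 control entered the calling are not given in the sources used here. The score was used to describe and rank peaks within the list.

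The files held 27052 gene entries, of which 26909 were matched to a locus code by name, symbol or synonym through a RefSeq table of the assembly TAIR10.1; that table served for names and gene order, and no coordinate was taken from it. The remaining 143 were used by position alone, and 13 names had been turned into dates. In the files 3373 entries (12.5%) share their locus interval with another entry. Coordinates are 1-based, from the authors' files.

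Ratios were log2 of FPKM + 1 in either library, and no test was run on them. An additive fit of genotype and copper over the 4 libraries would leave 1 residual degree of freedom and would take the difference between the copper ratios of the genotypes as error; it was not run. A gene was counted as higher or lower with at least 5 FPKM in either library and a ratio of at least 2-fold. For the difference between genotypes, the copper ratio of spl7 was subtracted from that of wild type, and genes were counted at a log2 size of at least 1 with 5 FPKM in any library. The median of each of 23 lists (262 genes) over members of at least 1 FPKM was placed among 10000 random lists of equal size, drawn from 20 bins of mean expression. The percentile describes these libraries and is no test of the conditions. The lists covered SPL7, copper uptake and reduction, copper chaperones and ATPases, superoxide dismutases, copper microRNA precursors and their targets, plastocyanins, metallothioneins, iron deficiency, ferritins, zinc deficiency, flavonoids, light signalling, antenna and Rubisco genes, oxidative stress, heat shock, salicylate defence, jasmonate, phosphate starvation, the clock, root markers, seed markers and reference genes. The 7 microRNA precursors, ZIP4, PAA2 and CAT2 were not matched and were not analysed here. Overlaps of gene lists were set beside the number shared by independent lists and beside 100 simulated sets of libraries with no effect.

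Genes were named by this rule: SPL7; the 10 highest and 10 lowest ratios among nuclear genes counted in a comparison; of each list the counted members, up to 4 by size; any member of the lists of SPL7, copper uptake, chaperones, superoxide dismutases and microRNA precursors; the 10 highest-scoring peaks (ties broken by width, which the rule had not stated); peaks at members of these copper lists; and the 10 largest ratios in either direction among genes with a peak that were counted in spl7 on MS. Genes outside it are said to be chosen after their values were seen.

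A gene was assigned to a peak by an overlap of at least 1 bp with the gene or the 1 kb on either side. Upstream regions had been planned, but the files give no strand. The share of peaks near genes was compared with 1000 random placements of the same widths on the same chromosomes. The motif content of peaks was planned and not analysed, since no genome sequence was used here.

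Pseudocounts of 0.1 and 5 FPKM, minimum levels of 1 and 20 FPKM or none, ratios of 1.5-fold and 4-fold, rescaled libraries, flanks of 500 bp and 3 kb, peak midpoints and the higher-scoring peaks were tried as alternatives, and others were added after seeing the data. The counting was tested on simulated data for spl7 against wild type on MS, over 18989 genes with normal noise and no values at 0. It counted 8% of 50 genes changed 1.5-fold, 44% at 2-fold, 96% at 3-fold and 92% at 4-fold, and 24 of 18789 unchanged genes; 94 of 100 random lists lay in the central 95% of their reference. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.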

Results

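Transcripts were measured by RNA-seq in whole Arabidopsis thaliana seedlings aged 7 days, either Col-0 wild type or the spl7 mutant, which carries a lesion in SPL7, a transcription factor of the SBP-domain family known as a regulator of copper homeostasis. Each genotype was grown on standard MS (Murashige and Skoog) medium or on MS with 5 µM added CuSO4, which gave 4 groups of 1 library. Binding was measured by ChIP-seq with a FLAG antibody in seedlings that carried a 35S:FLAG-SPL7 transgene, with spl7 seedlings as the negative control, and 1 list of peaks was analysed. The deposited FPKM (fragments per kilobase of transcript, scaled to library size) values summed to 4496210 in wild type on MS, 4402190 in wild type with copper, 4694640 in spl7 on MS and 4383940 in spl7 with copper. Their medians over 27052 gene entries were 29.8, 30.3, 29.3 and 29.8 FPKM. No library has a replicate, so no difference between these libraries has a replicate check, and no p-value is given. The number of reads behind each value is unknown. A gene was counted as higher or lower where it reached 5 FPKM in either library and its ratio of FPKM + 1 was at least 2-fold, and all log2 ratios are on that scale, which understates the change of low genes. An FPKM of exactly 0 is given as listed at 0, because genes used in most tissues were also listed at 0, among them the reference helicase gene AT1G58050 and the metallothionein gene MT1A, at 0 in all 4 libraries (both chosen after their values were seen).

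SPL7 itself (AT5G18830; TAIR10 chromosome 5, 6275990 to 6280681) stood at 107 FPKM in wild type on MS and 105 FPKM in wild type with copper. In spl7 it stood at 20.2 FPKM on MS and 20.7 FPKM with copper. The log2 ratio of mutant to wild type was -2.35 on MS and -2.28 with copper, so the labels of both genotypes matched the transcript of the mutated gene. Added copper left SPL7 at a log2 ratio of -0.04 in wild type and 0.04 in spl7.

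The first comparison asked how the loss of SPL7 altered transcripts on MS, where no copper was added. FSD1, the iron superoxide dismutase of the chloroplast (AT4G25100; chromosome 4, 12884300 to 12887011), stood at 5647 FPKM in wild type and 7.64 FPKM in spl7, a log2 ratio of -9.35. The copper/zinc superoxide dismutases went the other way: CSD1 (AT1G08830), the cytosolic enzyme, stood at 186 FPKM in wild type and 2090 FPKM in spl7, and CSD2 (AT2G28190), the chloroplast enzyme, at 466 and 4929 FPKM. Their chaperone CCS stood at 162 and 1040 FPKM, whereas the copper chaperone CCH stood at 2929 and 703 FPKM. CSD1 shares its locus in the files with another gene, emb2411.

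Of the 13 matched genes of copper uptake and reduction, 6 were lower in spl7 on MS, 0 were higher and 7 were not counted as changed. The copper transporter COPT2 stood at 153 FPKM in wild type and 19.8 FPKM in spl7, and the metal-nicotianamine transporters YSL2 and YSL3 at 301 against 13.6 FPKM and 128 against 55.5 FPKM. YSL2 shares its locus in the files with another gene. The transporter ZIP2, the reductase FRO4 and the transcription factor CITF1 (AT1G71200) stood at 96.5, 13.9 and 15.9 FPKM in wild type and were listed at 0 in spl7. COPT1 stood at 463 FPKM in wild type and 458 FPKM in spl7. The list had a median log2 ratio of -2.47, below all 10000 random lists of equal size matched on mean expression (percentile 0). Without the 4 measured members listed at 0 in spl7, ZIP2, FRO4, FRO5 and CITF1, the median was -0.02.

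Transcripts that are targets of copper-responsive microRNAs were higher in spl7 on MS in 5 of 13 cases and lower in 0, with a list median of 0.69 (percentile 100). Besides CSD1, CSD2 and CCS these were the plantacyanin ARPN, at 35.9 and 105 FPKM, and the laccase LAC2, at 1.79 and 6.75 FPKM. LAC2 lay outside the naming rule and was chosen after its values were seen. None of the 7 precursor genes of these microRNAs on the list was matched in the files, so their transcripts were not analysed here. Of the 10 matched copper chaperones and copper ATPases, CCS was higher, CCH was lower and 8 were not counted (list median 0.02). Of the 7 superoxide dismutases, CSD1 and CSD2 were higher, FSD1 was lower and 4 were not counted (list median -0.18). Neither plastocyanin, the copper proteins of photosynthetic electron transport, was counted.

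Among other nutrient lists on MS, 3 of 22 iron deficiency genes were lower in spl7 and 0 were higher, with a list median of -0.25 (percentile 0.02) that was -0.15 without members listed at 0. Root and root hair markers had a median of -0.19 (percentile 0.71) in the same comparison, with 0 of 13 counted, and genes of the iron and copper uptake lists, IRT1, FRO2 and COPT2 among them, are known to act in roots. The iron transporter IRT1 stood at 61.7 FPKM in wild type and 20.2 FPKM in spl7, the ferric reductase FRO2 at 30.0 and 11.9 FPKM, and CYP82C4 at 20.9 and 1.90 FPKM. In the phosphate starvation list, 2 of 9 genes were higher, the noncoding transcript IPS1 (42.0 and 101 FPKM) and the galactolipid synthase MGDC (39.5 and 93.5 FPKM), and the median was 0.54 (percentile 100). The jasmonate list had a median of 0.45 (percentile 100) with 1 of 11 genes counted as higher, VSP2 at 34.3 and 83.01 FPKM. The photosystem antenna and Rubisco list had a median of 0.21 (percentile 99.9) with 0 of 22 genes counted, and the zinc deficiency list one of 0.26 (percentile 98.8) with 0 of 8 counted. The clock gene ELF4 was lower, at 16.4 FPKM in wild type and 4.41 FPKM in spl7, and the heat shock gene HSP17.6C (AT1G53540) was higher, at 8.01 and 20.0 FPKM. Seed storage and late embryogenesis markers moved with genotype as well: 2 of 11 were lower in spl7, and their median was -0.71 (percentile 0). SESA3 stood at 23.0 and 6.49 FPKM, and the cruciferin CRU2 stood at 5.51 FPKM in wild type and was listed at 0 in spl7.

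In all, 101 genes were higher and 196 lower in spl7 than in wild type on MS, of 18658 genes that reached 5 FPKM in either library. Of these, 46 higher and 79 lower genes were listed at 0 in 1 of the libraries. Apart from copper genes, the genes with the largest ratios included QQS (AT3G30720), a regulator of starch content, at 15.1 FPKM in wild type and 469 FPKM in spl7, and MAPR2, at 0.00373 and 38.8 FPKM, which shares its locus with another gene. On the lower side AT2G33850 stood at 396 and 10.2 FPKM and AT2G25625 at 114 and 2.77 FPKM. AT5G33370, LCR67 and the heme oxygenase gene HO3 stood at 65.2, 41.1 and 22.0 FPKM in wild type and were listed at 0 in spl7. AT1G24388 stood at 66.2 FPKM in wild type and at 0 in spl7, and shares its locus with another gene. When libraries with no real difference were simulated from the spread of all genes, which includes real effects and values at 0, a mean of 384 genes was counted, more than the 297 observed. With normal noise of the central spread, a version added after that result was seen, the mean was 39.1 genes, so the counts alone do not separate an effect of genotype from noise.

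**Figure D1:**
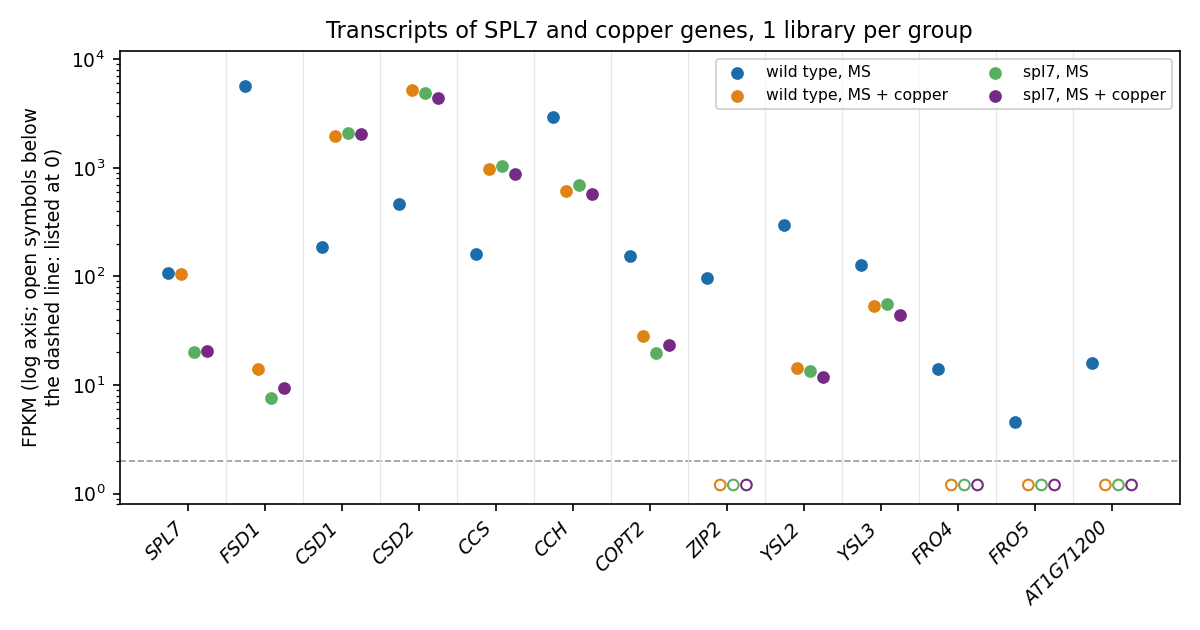
FPKM of SPL7 and 12 copper genes in the 4 libraries on a log axis, 1 symbol per library, with open symbols below the dashed line for values listed at 0. FSD1 stood at 5647 FPKM in wild type on MS and between 7.64 and 14.0 FPKM in the other libraries, whereas CSD1, CSD2 and CCS were lowest in wild type on MS.

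The second comparison made the same contrast of genotypes with added copper. SPL7 apart, 0 of 13 copper uptake genes, 0 of 10 copper chaperones and ATPases, 0 of 7 superoxide dismutases and 0 of 13 microRNA targets were counted as changed. FSD1 stood at 14.0 FPKM in wild type and 9.38 FPKM in spl7, CSD2 at 5164 and 4444 FPKM, CSD1 at 1985 and 2035 FPKM, and COPT2 at 28.5 and 23.5 FPKM. ZIP2, FRO4, FRO5 and CITF1 were listed at 0 in both. The copper uptake list had a median log2 ratio of -0.07 (percentile 29.7) and the microRNA target list one of -0.04 (percentile 43.1).

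Stress and defence lists were higher in spl7 with added copper. Of 17 matched oxidative stress genes, 4 were higher and 0 lower, with a median of 0.35 (percentile 100): the glutathione transferases GSTF7 (45.6 FPKM in wild type, 259 FPKM in spl7), GSTU4 (19.2 and 103 FPKM), GSTU25 (38.8 and 117 FPKM) and GSTF6 (79.0 and 188 FPKM). GSTF6 and GSTF7 are close copies whose reads are hard to tell apart. Of 10 salicylate defence genes, 3 were higher and 0 lower: the camalexin enzyme PAD3 stood at 3.64 and 53.8 FPKM, the transcription factor WRKY70 at 15.1 and 32.4 FPKM and CBP60G at 14.0 and 31.6 FPKM. That list had a median of 0.70 (percentile 100), which was 0.22 without members listed at 0. The jasmonate list had a median of 0.38 (percentile 100) with VSP1 higher, at 21.7 and 50.6 FPKM, and the heat shock list one of 0.30 with 0 of 12 genes counted. The iron deficiency list had a median of -0.28 (percentile 0.01), with CYP82C4 lower at 18.4 and 7.65 FPKM, beside a root marker median of -0.16 (percentile 2.81). Beside these lists, seed storage markers were lower in 6 of 11 cases, with a median of -1.42 (percentile 0) that was -0.20 without members listed at 0. SESA3 stood at 46.7 and 6.21 FPKM, and SESA2, CRU2 and SESA4 stood at 43.4, 9.78 and 5.17 FPKM in wild type and were listed at 0 in spl7.

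With copper, 186 genes were higher and 153 lower in spl7, of 18805. Of these, 51 higher and 88 lower genes were listed at 0 in 1 of the libraries, and without genes listed at 0 there were 135 higher and 65 lower. The 339 in all were fewer than the mean of 381 in libraries simulated with the spread of all genes and more than the 39.55 with normal noise. Again QQS (13.8 and 357 FPKM) and MAPR2 (0.587 and 26.6 FPKM) were higher, and AT2G33850 (386 and 5.97 FPKM) was lower. The wild-type value of MAPR2 again lay below the first percentile of values above 0 in its library (1.63 FPKM), so its ratio has the same limit. LCR67 and AT5G33370 stood at 85.4 and 65.5 FPKM in wild type and at 0 in spl7. ALD1, an enzyme of pipecolic acid synthesis, and the phosphate transporter PHT3;2 were listed at 0 in wild type and stood at 14.7 and 18.1 FPKM in spl7. Of the 10 highest ratios 8, and of the 10 lowest 9, involved a library at 0. The 2 genotype comparisons shared 64 lower and 18 higher genes, where independent lists would share 1.11 and 0.472. Simulated libraries with no difference shared a mean of 8.95 and 8.99 genes with the spread of all genes, and 0.38 and 0.26 with normal noise.

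**Figure D2:**
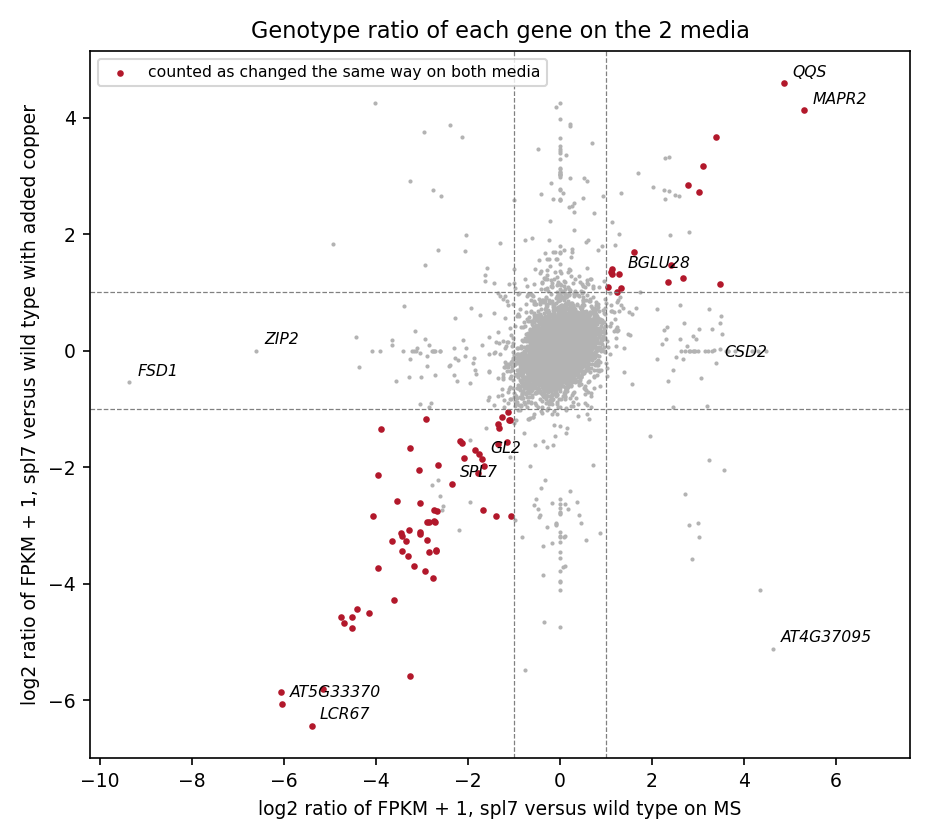
Log2 ratio of spl7 to wild type on MS (horizontal) and with added copper (vertical), both of FPKM + 1, for genes that reached 5 FPKM in any library, with dashed lines at 2-fold. Red points are the 18 higher and 64 lower genes counted as changed the same way on both media, and FSD1 and ZIP2 lie far to the left near 0 on the vertical axis.

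The third comparison asked how added copper altered transcripts in wild type. FSD1 stood at 5647 FPKM on MS and 14.0 FPKM with copper, a log2 ratio of -8.55. CSD2 stood at 466 and 5164 FPKM, CSD1 at 186 and 1985 FPKM, CCS at 162 and 981 FPKM, and CCH at 2929 and 615 FPKM. Of the 13 copper uptake genes 6 were lower with copper and 0 higher: COPT2 stood at 153 and 28.5 FPKM, YSL2 at 301 and 14.5 FPKM and YSL3 at 128 and 54.0 FPKM. ZIP2, CITF1 and FRO4 were listed at 0 with copper. The list had a median of -2.39 (percentile 0), which was -0.44 without members listed at 0. Of the 13 microRNA targets 4 were higher and 0 lower, with a median of 0.36 (percentile 100), and ARPN stood at 35.9 and 172 FPKM. Of the 22 iron deficiency genes 1 was higher with copper, the nicotianamine synthase gene NAS2 at 3.92 and 14.3 FPKM, and 0 were lower, whereas the list median was -0.17 (percentile 0.02), beside a root marker median of -0.11 (percentile 1.15).

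Seed storage markers were higher with copper in 6 of 11 cases in wild type, with a median of 1.05 (percentile 100): EM1 stood at 5.45 and 17.8 FPKM, SESA1 at 24.0 and 60.7 FPKM and SESA2 at 7.94 and 43.4 FPKM. The oxidative stress list had a median of 0.31 (percentile 100), with 1 of 17 genes counted, GSTU24 at 177 and 457 FPKM. The salicylate and heat shock lists had medians of 0.30 and 0.25 with 0 genes counted in each, and the antenna and Rubisco list one of -0.11 (percentile 0.01) with 0 of 22 counted. In all, 178 genes were higher and 71 lower with copper, of 18742, of which 54 higher and 30 lower genes were listed at 0 in 1 of the libraries. The 249 compare with a mean of 386 in simulated libraries with the spread of all genes and 39.1 with normal noise. Of the 10 highest ratios 8 belonged to CPuORF entries, conserved upstream open reading frames annotated inside other genes: CPuORF19, for example, stood at 0.0957 FPKM on MS and 389 FPKM with copper. Each CPuORF entry shares its locus with another entry, and the closing section describes them. The small gene AT4G37095 was listed at 0 on MS and stood at 33.6 FPKM with copper.

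The genes lower in spl7 on MS and those lower with copper in wild type were compared directly. They shared 34 genes, FSD1, CCH, COPT2, ZIP2, YSL2, YSL3, FRO4 and CITF1 among them, and the higher genes shared 28, CSD1, CSD2, CCS and ARPN among them. Independent lists would share 0.751 and 0.295. Both comparisons use the wild-type library on MS, so simulated libraries with no effect also shared genes: a mean of 115 lower and 43.2 higher with the spread of all genes, and 5.10 and 1.47 with normal noise. The first simulation overstates noise and the second leaves out values at 0, so part of the excess over independent lists may come from the shared library. In all, 27 genes were at least 2-fold higher in wild type on MS than in each other library, and 39 at least 2-fold lower.

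The fourth comparison asked how added copper altered transcripts in spl7. None of the 13 copper uptake genes, 7 superoxide dismutases and 13 microRNA targets was counted as changed. FSD1 stood at 7.64 FPKM on MS and 9.38 FPKM with copper, CSD2 at 4929 and 4444 FPKM and COPT2 at 19.8 and 23.5 FPKM. The copper ATPase HMA5 was higher with copper, at 28.4 and 66.9 FPKM, and so was the mitochondrial copper chaperone COX17, at 44.6 and 94.3 FPKM, which shares its locus with the metallothionein gene MT3.

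Oxidative stress genes were higher with copper in spl7 in 9 of 17 cases and lower in 0, with a median of 1.03 (percentile 100). GSTF7 stood at 31.9 and 259 FPKM, GSTU25 at 21.5 and 117 FPKM, GSTU4 at 26.5 and 103 FPKM and GSTF6 at 59.5 and 188 FPKM. Salicylate defence genes were higher in 4 of 10 cases, with a median of 1.83 (percentile 100) that was 0.58 without members listed at 0: PAD3 stood at 4.90 and 53.8 FPKM, WRKY70 at 7.76 and 32.4 FPKM and CBP60G at 8.87 and 31.6 FPKM, and BGL2, the glucanase PR2, was listed at 0 on MS and stood at 5.81 FPKM with copper. The heat shock list had a median of 0.43 with 0 of 12 genes counted. The phosphate starvation list had a median of -0.42 (percentile 0) and the antenna and Rubisco list one of -0.27 (percentile 0.01), with 0 genes counted in either. Iron genes went both ways: BHLH100 stood at 41.8 and 12.5 FPKM and BHLH038 at 67.2 and 21.0 FPKM, whereas CYP82C4 stood at 1.90 and 7.65 FPKM and NAS2 was listed at 0 on MS and stood at 10.6 FPKM with copper. The zinc deficiency gene NAS3 was lower, at 154 and 59.8 FPKM, and ELF4 was higher, at 4.41 and 16.4 FPKM. Beside these lists, seed storage markers were higher in 5 of 11 cases, with a median of 1.09 (percentile 100), CRA1 at 102 and 331 FPKM and CRU3 at 49.9 and 133 FPKM.

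With copper 372 genes were higher and 98 lower in spl7, of 18707. Without the 78 higher and 49 lower genes listed at 0 in 1 of the libraries there were 294 and 49. The 470 in all exceeded the means of simulated libraries with no difference, 381 with the spread of all genes and 39.1 with normal noise. In the other 3 comparisons the first mean exceeded the count. That first mean was drawn from all libraries together, real effects included, and ran only from 381 to 386 over the comparisons. The comparison with the most counted genes therefore stands highest against it, and the excess does not separate an effect of copper from noise. AT4G12490 stood at 11.4 and 603 FPKM. AT2G04070 and PNP-A, a plant natriuretic peptide, were listed at 0 on MS and stood at 92.6 and 47.7 FPKM with copper. All 10 of the lowest ratios involved a library at 0, and 7 of the 10 highest belonged to CPuORF entries. The 2 copper comparisons shared 87 higher and 11 lower genes, where independent lists would share 2.41 and 0.187, and simulated libraries shared 8.69 and 9.42 with the spread of all genes or 0.33 and 0.19 with normal noise. The library of spl7 with copper was at least 2-fold above each other library for 108 genes, against 27 for wild type on MS, 32 for wild type with copper and 22 for spl7 on MS. The library of spl7 on MS, against which these copper ratios were taken, was at least 2-fold below each other library for 73 genes, against 39, 21 and 41 for wild type on MS, wild type with copper and spl7 with copper. Of the 372 higher genes, 108 were high in spl7 with copper alone, 58 were low in spl7 on MS alone, with some genes in both sets, and 218 were in neither.

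**Figure D3:**
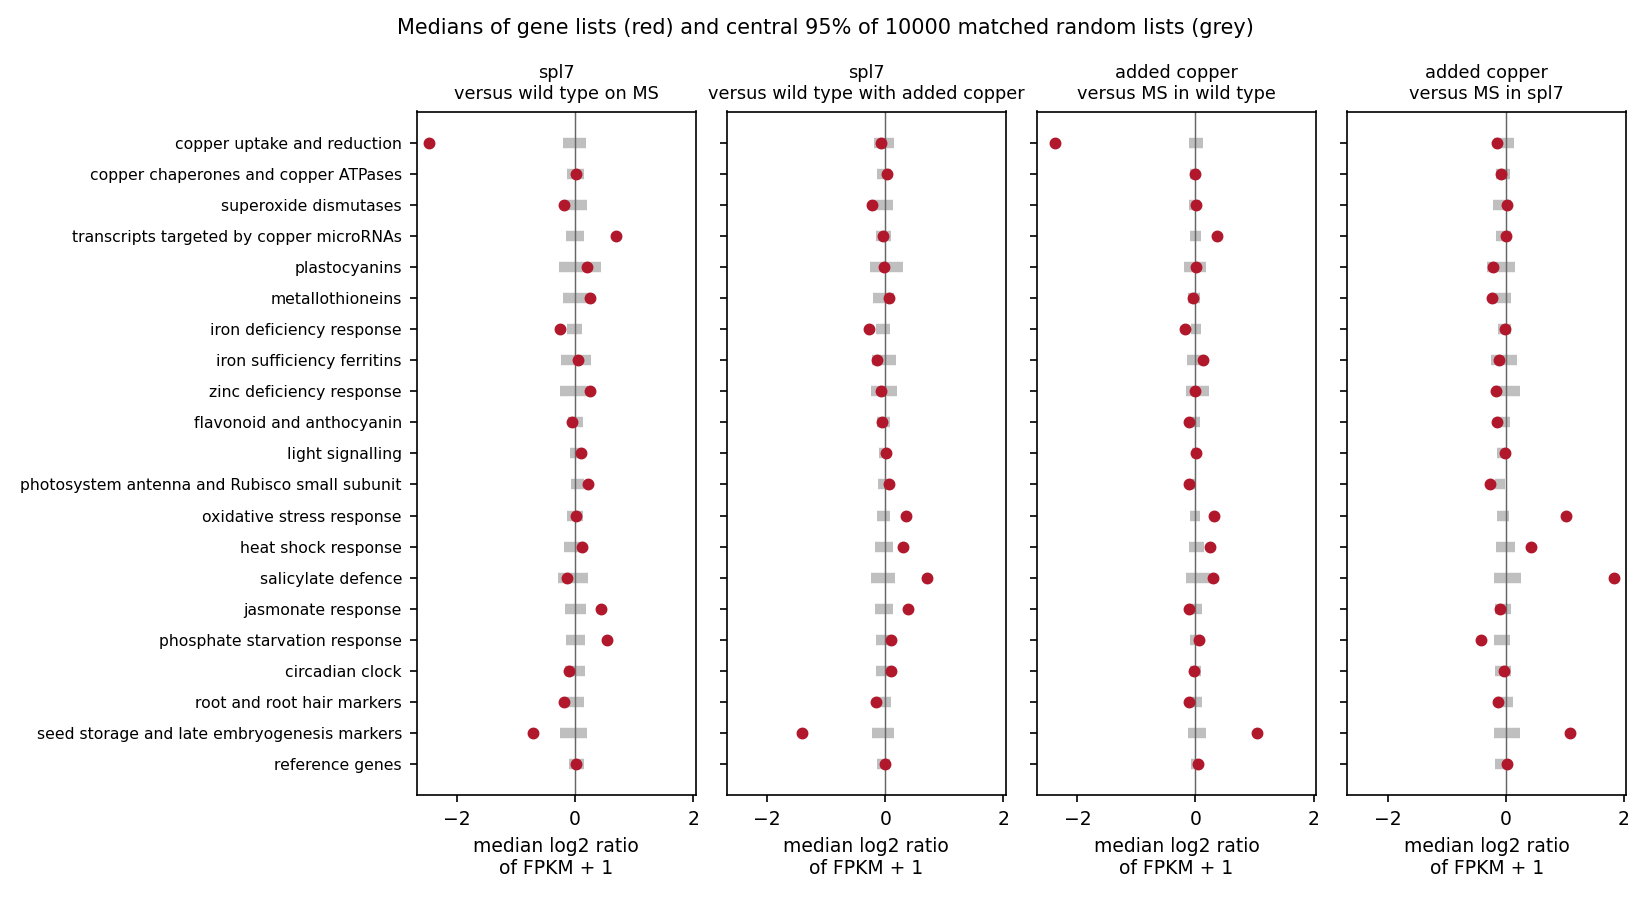
Median log2 ratio of FPKM + 1 of each gene list (red) in the 4 comparisons, with the central 95% of 10000 expression-matched random lists (grey), on 1 scale for all panels. The copper uptake list lies at -2.47 on MS between genotypes and at -2.39 with copper in wild type, and the salicylate list at 1.83 with copper in spl7.

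The difference between the copper ratios of the genotypes, wild type minus spl7, was at least 1 on the log2 scale for 182 genes and at most -1 for 298, of 18989 that reached 5 FPKM in any library. Of these, 99 and 100 genes were listed at 0 in at least 1 library, and without such genes there were 83 and 198. It was -8.82 for FSD1, -2.62 for COPT2, -4.10 for YSL2 and -1.97 for CCH, and 3.62 for CSD2, 3.45 for CSD1 and 2.82 for CCS. The copper uptake list had a median of -2.47 (-0.34 without members listed at 0), the microRNA target list 0.66, the phosphate starvation list 0.53, the oxidative stress list -0.25 and the salicylate list -1.04. Seed storage markers had a median of 0.64, which turned to -0.30 without members listed at 0. The difference was not tested, for lack of replicates.

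Of the 14 reference genes 0 were counted in any comparison of 2 libraries, and ACT2, chosen after its values were seen, stood at 2403, 2571, 2546 and 2576 FPKM in wild type on MS, wild type with copper, spl7 on MS and spl7 with copper. No metallothionein, ferritin, plastocyanin, flavonoid, light signalling or root marker gene was counted either. Between genotypes on MS the list medians were 0.26 for metallothioneins, 0.04 for ferritins, 0.20 for plastocyanins, -0.05 for flavonoid genes, 0.09 for light signalling, -0.19 for root markers, -0.11 for clock genes, 0.11 for heat shock genes, 0.02 for oxidative stress genes, -0.14 for salicylate defence genes and 0.01 for reference genes. The heat shock, oxidative stress and salicylate medians on MS lay inside their random ranges, unlike those with copper. The flavonoid median was -0.11 with copper in wild type (percentile 0.49) and -0.15 in spl7 (percentile 1.53), and the reference genes had 0.04 with copper in wild type (percentile 98.1).

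The ChIP-seq list was used to ask where in the genome FLAG-SPL7 was enriched. It held 1535 peaks with a median width of 357 bp and scores, as the authors deposited them, from 164.95 to 3126.1. Of these, 1371 (89.3%, Wilson 95% interval 87.7 to 90.8, counting error only) lay over or within 1 kb of a gene, against a mean of 75.0% (71.5 to 78.2) in 1000 random placements. The highest score belonged to a peak over carbonic anhydrase CA1 (chromosome 3, 194937 to 196698), and 24 peaks were tied at 3100. Of these 25 peaks, 23 lay over a gene, 22 over a gene of the highest 10% by mean FPKM and 9 over an antenna or Rubisco gene. The 9 widest of the tied peaks were named: they lay over the magnesium chelatase gene GUN5, the aldolase gene FBA2, Rubisco activase RCA, phosphoribulokinase PRK, the cyclase gene CRD1, ADC2 and AT5G25280, and beside AT4G35080 and AT2G07687, which was listed at 0 in all 4 libraries. CRD1 shares its locus in the files with SIP2;1. The catalase gene CAT2, whose locus code lies close to that of AT4G35080, was not matched in the files. A peak over such a missing gene would be counted as beside another gene or as without a gene. The densest run of peaks in any 250 kb lay on chromosome 2 (3260314 to 3501978), with 119 peaks, against at most 21 in a window elsewhere. It held 56 of the 164 peaks without a gene within 1 kb, and 2 of its 53 genes reached a mean of 1 FPKM. Only uniquely mapped RNA-seq reads were kept, so a low FPKM there need not mean low transcription.

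All 22 antenna and Rubisco genes had a peak within 1 kb, whereas 0 of 13 copper uptake genes had one. FSD1 had 3 peaks (scores 180.94, 235.51 and 211.16), CSD2 1 peak (chromosome 2, 12014504 to 12014846, score 229.03), CCH 1 peak (chromosome 3, 20863422 to 20863788, score 207.74) and COX17 2, at the locus it shares with MT3 (scores 534.49 and 282.47). By score the FSD1 peaks ranked 1422, 705 and 855 of 1535, the CSD2 peak 736 and the CCH peak 895. The median score of the list was 223.61, so the peaks at FSD1, CSD2 and CCH did not stand out by score. SPL7 had 6 peaks, the highest at chromosome 5, 6275987 to 6276756, with a score of 1104.04, and the transgene itself carries SPL7 sequence. A peak was found within 1 kb of 34.2% of genes in the highest of 10 equal groups by mean FPKM and of 7.97% of all genes of at least 1 FPKM.

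Of 1813 genes with a peak over the gene or within 1 kb on either side, 5 were higher and 8 lower in spl7 on MS. Together these 13 lay inside the range of 8 to 21 that covers 95% of expression-matched random lists, whereas the median log2 ratio of the peak genes, 0.0341, lay above its range of 0.00259 to 0.02502. The genes with the largest ratios were FSD1, MAPR2, CSD2, AT2G47010 (41.0 FPKM in wild type, 5.41 FPKM in spl7), SPL7, CCH, AT5G14550 (66.4 and 17.1 FPKM), the homeobox gene GL2 (31.0 and 8.95 FPKM), AT3G54060 (10.2 and 2.59 FPKM) and PDF1.4 (44.8 and 16.9 FPKM). Of these MAPR2, AT5G14550, GL2 and AT3G54060 share their locus with another gene. As described above, the wild-type value of MAPR2 on MS cannot be taken as a measured level. The numbers counted as changed in the other comparisons were 9 between genotypes with copper (random 8 to 21), 18 with copper in wild type (5 to 17) and 18 with copper in spl7 (12 to 28). The medians were -0.0197 (random -0.0404 to -0.0219), -0.0205 (-0.0189 to -0.00728) and -0.0703 (-0.0635 to -0.0458) in the same order, all small and outside their ranges. The random lists were matched in 20 bins of mean expression, and the highest 10% of genes alone ran from 365 to 73070 FPKM. Since 34.2% of those genes had a peak, matching is coarse where peak genes are frequent. Whether this gives the small shifts of the medians was not tested.

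**Figure D4:**
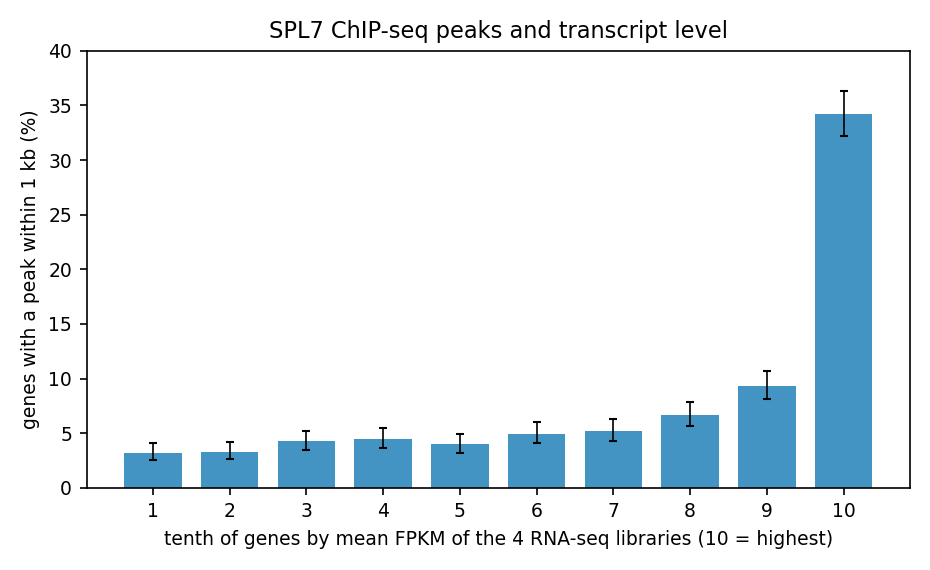
Share of genes with a ChIP-seq peak within 1 kb, in 10 equal groups of genes ordered by mean FPKM over the 4 RNA-seq libraries, with Wilson 95% intervals that cover counting error only. The share was 3.20% in the lowest group, 9.35% in the group below the highest and 34.2% in the highest.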

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

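Of the tests in this part, those of peaks against transcript level, of peak genes against genotype and of peaks at copper-responsive genes, that of the other genes at CPuORF loci and that of a stretch of chromosome were chosen after the results were seen.

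Between media 15 genes differed in opposite directions in the genotypes: 7 were counted as higher with copper in wild type and lower in spl7, and 8 as lower in wild type and higher in spl7. The difference was not tested. Independent lists would share 0.542 and 0.832 genes in these directions, and simulated libraries with no effect shared 9.13 and 9.12 with the spread of all genes or 0.18 and 0.18 with normal noise. A value of 0 entered for 10 of the 15. The other 5 genes had log2 copper ratios that differed, wild type minus spl7, by -6.76 for AT2G25625, -2.15 for AT2G47640, -2.93 for AT3G54060, -4.02 for LAP3 and 3.43 for RBL13. In wild type on MS, wild type with copper, spl7 on MS and spl7 with copper, AT2G25625 stood at 114, 4.90, 2.77 and 20.0 FPKM. In the same order LAP3 stood at 35.1, 6.46, 7.78 and 28.5 FPKM and RBL13 at 8.67, 39.0, 36.7 and 13.5 FPKM. This pair shares 1 locus in the files (chromosome 3, 21991826 to 21995308). In each library LAP3 was high where RBL13 was low. A changed division of fragments between these overlapping entries could give both ratios, so neither can be read as a copper response of its gene. AT2G47640 and AT3G54060 also share their loci with other genes.

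Of the 25 ChIP-seq peaks with the highest scores 22 lay over genes of the highest 10% by expression, and the share of genes with a peak within 1 kb was 4.29 times as high in that 10% as over all genes of at least 1 FPKM. Across 1064 genes with a peak, the Spearman correlation of peak score with mean FPKM was 0.47. The 1138 genes under a peak had a median of mean FPKM of 470, against 29.8 for all 27052 entries. Peak signal and transcript level thus went together in this list, but these values include the genes that showed the pattern. As the cause, ChIP signal that follows transcript level stays open. Among the other 90% of genes, the share in the 10% of all genes just below the highest was 1.85 times that of the whole 90%. That lay between the 3 times set as needed and the 1.5 set as against it. The share rose from 3.20% in the lowest 10% of genes (Wilson 95% interval 2.52 to 4.07) to 9.35% (8.15 to 10.7) just below the highest. In the dense run on chromosome 2, 119 peaks lay where 2 of 53 genes reached 1 FPKM. This run cannot decide the question: only uniquely mapped reads were kept, so a low FPKM there need not mean low transcription. That SPL7 sets the transcript level of the peak genes as a group stays open too. Without SPL7 itself, which is the mutated gene and was left out here after the values were seen, 12 of 1595 such genes were counted as changed between genotypes on MS, inside the 8 to 20 of random lists, but with peaks over the gene body 11 were (random lists 3 to 12), closer to the upper bound than the random SD of 2.32. With SPL7 kept, the gene-body counts were 12 changed (3 to 12) and 7 lower (0 to 7), and with copper in wild type 5 were lower (0 to 4). By the bound first written down the counts on MS, none of them above that of random lists, argued against the explanation, and they were read as open only after they were seen. The median log2 ratio of the 1595 genes, 0.0342, lay above the random range of 0.00241 to 0.02504 and rests on 1 library of each genotype. The coarse matching of random lists among the most highly expressed genes limits this median too. Occupancy at copper-responsive genes stays open too, since 4 of the 27 genes at least 2-fold higher in wild type on MS than in each other library had a peak, equal to the upper bound of 4 for random lists. Those lists were matched on mean log2 expression over all RNA-seq libraries, which is below the level of the 27 genes in wild type on MS. The bound may therefore be too low. By the bound first written down this count, at the upper bound of random lists, argued against occupancy with no margin, and it was read as open only after the value was seen. For these genes SPL7 occupancy and chance cannot be told apart, since 27 genes are few and the control was not analysed here.

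CPuORF entries made up 8 of the 10 highest copper ratios in wild type, and 14 of 58 were higher with copper in wild type, 11 in spl7 and 10 in both, with a median log2 ratio of 4.76 for those 14 in wild type. A copper response of the whole locus is argued against: the 16 entries other than CPuORF at these loci, of at least 5 FPKM, had a median log2 ratio of -0.037 (from -0.41 to 0.12). Of the 144 values above 0 and under 0.5 FPKM, 97.2% belonged to entries that share a locus, against 12.5% of all entries, so fragments divided between overlapping gene models are a candidate explanation. The 144 include values of the CPuORF entries that raised the question, and all 58 CPuORF entries share a locus, so the 97.2% is not independent of the pattern. On MS the 10 entries higher in both genotypes stood at 0.0361 to 0.163 FPKM in wild type and 0.0423 to 0.149 FPKM in spl7. Each of these values lay below the first percentile of the values above 0 in its library. They cannot be taken as measured levels, so the ratios cannot be read as a copper response of the upstream frames. Why the division would differ between media was not tested. Whether copper acts on the frames themselves cannot be decided from these entries, since their values on MS cannot be taken as measured levels. With 1 library per group, copper also cannot be told apart from any other difference between the MS and the copper libraries.

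Among the 64 genes lower in spl7 on both media 9 trichome and cuticle genes were noticed: CER1 stood at 121 FPKM in wild type and 37.6 FPKM in spl7 on MS, CYP86A4 at 35.7 and 4.87 FPKM and MYB23 at 15.6 and 3.82 FPKM, all chosen after their values were seen. A list was then built around the 9, and its 29 other measured genes had medians of -0.12 on MS and -0.17 with copper, at percentiles 1.16 and 0.06 of random lists, which is consistent with a lower share or activity of these programmes. None of the 29 was counted on either medium, but genes seen as lower had been set apart, so the size of the change cannot be read from them. On MS the shift was not particular to these programmes, with medians of -0.19 for root markers (percentile 0.71) and -0.71 for seed markers (percentile 0). With copper the root median of -0.16 lay inside its random range (percentile 2.81), and the seed median of -1.42 (percentile 0) was -0.20 without members at 0. A lower share of young dividing tissue stays open, with 12 cell division and young leaf genes at percentiles 3.21 and 1.93. One deleted or exchanged stretch of chromosome as the source of all 64 genes lower on both media is argued against. Of these, 21, 7, 9, 11 and 16 lay on chromosomes 1 to 5, and 0% lay within 3 entries of another such gene (random mean 1.39%). Loss of single genes, or an exchanged stretch whose lower genes lie further apart, would not be seen by this count. Genotype itself, with 1 library per medium, stays open and was not tested further.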

How the results depend on the processing

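Settings that left out genes at 0, genes that share a locus, CPuORF entries, list members at 0 or SPL7 from the peak genes, and the gene-body definition of peak genes, were chosen after the data were seen. No library was left out, since each group has 1, and no paired analysis was possible because each group has 1 library, as far as pairing by replicate goes. Genotype could be paired within medium and copper within genotype in an additive fit over the 4 libraries, with 1 residual degree of freedom, but that fit was not run. Of the gene counts, 59 stayed within 1.5 times the value reported and 61 did not; of the list medians 391 moved by less than 1 SD of random lists, 28 moved further and 1 reversed; of the peak results 26 stayed near the value reported and 23 did not. Of the single genes named, 360 values stayed and 264 moved. Both rescalings of the libraries left every gene count within 1.5 times.

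Gene counts are given as higher and lower for spl7 against wild type on MS, then with copper, then copper in wild type, copper in spl7 and the difference. With 1 FPKM as the minimum they were 308 and 397, 331 and 395, 390 and 205, 565 and 332, and 475 and 516. With no minimum they were 308 and 397, 331 and 395, 390 and 205, 565 and 332, and 477 and 517. With 20 FPKM they were 34 and 61, 88 and 47, 83 and 25, 202 and 30, and 46 and 122. At 1.5-fold they were 440 and 590, 494 and 387, 472 and 217, 839 and 354, and 541 and 736. At 4-fold they were 59 and 99, 66 and 100, 85 and 39, 146 and 52, and 101 and 115. These follow from the construction of each setting. A pseudocount of 5 gave 130 lower on MS and 107 higher and 189 lower for the difference. Without genes at 0 the counts that moved were 55 and 117 on MS, 65 lower with copper, 41 lower for copper in wild type, 49 lower for copper in spl7, and 83 and 198 for the difference. Without genes that share a locus, 47 were lower with copper in wild type.

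With a pseudocount of 0.1, list medians became -2.95 for copper uptake on MS and -2.67 for its difference, -1.54 for seed markers between genotypes with copper and 0.46 for microRNA targets with copper in wild type. With 5 FPKM as the minimum, copper uptake had -2.04 on MS, -1.81 with copper in wild type and -1.76 for the difference; microRNA targets 0.80 on MS and 0.78 for the difference; iron deficiency -0.15 on MS, -0.22 with copper in wild type and -0.078 in spl7; salicylate defence 0.22 between genotypes with copper, 0.15 and 1.15 with copper in wild type and spl7 and -0.57 for the difference; seed markers 1.204 with copper in spl7; and zinc deficiency 0.30 for the difference. Without members at 0, copper uptake had -0.025 on MS, -0.44 with copper in wild type and -0.34 for the difference; iron deficiency -0.15 on MS and -0.12 with copper in spl7; salicylate defence 0.22 between genotypes with copper, 0.58 with copper in spl7 and -0.78 for the difference; and seed markers -0.20 between genotypes with copper and 1.204 with copper in spl7. The difference for seed markers reversed, from 0.64 to -0.30. The cause was not tested.

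The share of peaks near a gene was 85.9% at 500 bp, 94.6% at 3 kb and 86.7% for the higher-scoring 767 peaks. Genes with a peak numbered 2897 at 3 kb, 1148 where the peak reached into a flank, 1138 over the gene body and 929 for the higher-scoring peaks. Of these, genes counted on MS were 8 higher and 15 lower at 3 kb, 0 higher with a peak that reached into a flank and 3 higher for the higher-scoring peaks, and 15 higher and 13 lower with 1 FPKM as the minimum. Between genotypes with copper 22 were counted at 3 kb, 4 with a peak that reached into a flank and 20 with 1 FPKM. With copper in wild type 29 were counted with 1 FPKM, 10 over the gene body and 11 for the higher-scoring peaks. With copper in spl7 the counts were 38 at 3 kb, 33 with 1 FPKM, 9 over the gene body and 10 for the higher-scoring peaks. The alternatives for motifs were not run, as no genome sequence was used, and neither was that without peaks far from genes, whose share is 100% by construction; both flanks replaced the upstream region. Unknown depth limits all low values.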

Other observations

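AT5G14550 and AT2G47010 are named under the rule fixed beforehand, and the other genes named here were chosen after their values were seen. The test of sulfur deficiency genes was written down before its result was seen.

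Copper-responsive microRNA precursors were not matched, but 22 entries within 3 genes of them in the reference order were. Of these 14 reached 5 FPKM in a library, of which 2 were at least 2-fold higher in wild type on MS than in each other library and 12 had no 2-fold ratio in any comparison; 5 of the 22 had a peak within 1 kb, and 4 were at 0 throughout. Those 2 were AT5G14550 and AT2G47010. AT5G14550 (chromosome 5, 4691006 to 4694086), next to MIR398B in the reference order, stood at 66.4 FPKM in wild type on MS and at 18.4, 17.1 and 15.7 FPKM in wild type with copper, spl7 on MS and spl7 with copper. It shares its locus with another gene, and a peak with a score of 742.91 lay over it (chromosome 5, 4690462 to 4691151). AT2G47010 (chromosome 2, 19317126 to 19319397), 2 genes from MIR408, stood at 41.0, 7.66, 5.41 and 5.46 FPKM in the same order, and a peak with a score of 283.41 lay beside it (chromosome 2, 19319530 to 19319925). The same peak overlapped AT2G47020, the nearer neighbour of MIR408, which stood at 31.6, 20.9, 22.3 and 20.2 FPKM. UNE15, next to MIR397B, stood at 4.49 FPKM in wild type on MS and was listed at 0 in the other 3 libraries, with no peak within 1 kb.

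BGLU28 and DIN2, which encode beta-glucosidases, were higher in spl7 on both media: BGLU28 stood at 766 and 1871 FPKM on MS and 647 and 1615 FPKM with copper, and DIN2 at 845 and 1862 FPKM on MS and 613 and 1623 FPKM with copper. BGLU28 is a known marker of sulfur deficiency, so a sulfur deficiency response in spl7 was tested as a hypothesis on 10 other sulfur deficiency genes. Their median log2 ratio was 0.45 on MS and 0.45 with copper, at percentiles 100 and 100 of random lists, and 10 of 10 lay above 0 on both media. In wild type and spl7, LSU1 stood at 2774 and 5474 FPKM on MS, ATSDI1 at 2369 and 4088 FPKM and AT5G26220, a glutamylcyclotransferase, at 728 and 1194 FPKM. For copper against MS the same genes had medians of -0.17 in wild type and -0.31 in spl7. The values are consistent with such a response, but sulfur itself was not measured, 0 of the 10 passed the 2-fold rule, and each genotype has 1 library per medium.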
